A study of Mus musculus with 4 samples.

How the data were processed

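Single-cell 3' RNA libraries from 4 groups of mice with orthotopic SCLC were used, 1 library per group: control, anti-PD-1, YKL-5-124 and the combination. Per the labels, lungs were perfused and digested whole, and live cells were sorted on DAPI. How many animals went into a library is not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode as whole numbers, with no normalization, and are not restricted to cells. Per the submitters' processing notes, bcl2fastq and Cell Ranger made them, and the file headers give software version 3.0.0. The notes name the human build hg19, whereas every gene ID in the deposited feature table is a mouse Ensembl ID. The build and annotation release behind the count matrices are not given in the sources used here. Gene symbols were taken from the feature table. Of its IDs, 30934 were found in GENCODE release M21 (GRCm38), which gave the locations, transcript lengths and 3' ends, and 119 were not.

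Barcodes were kept as cells with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Doublets were scored per library with Scrublet in Scanpy 1.11.5. Its automatic threshold marked under 0.5% of each library, so the highest scores up to 0.8% per 1000 cells were removed instead, 97, 60, 138 and 131 cells in control, anti-PD-1, YKL-5-124 and the combination. Cells of all libraries were clustered together without integration, from 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). A cluster took the class whose fixed markers were highest in it, with at least 3 of them found in at least 10% of its cells and at least 2-fold above the other clusters. It stayed unnamed otherwise, or if its 10 leading genes held more markers of another class, or if it was shallow with no marker among them. The 2 unnamed clusters had enough neutrophil markers but leading genes of another class. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and Matplotlib 3.10.9 were used, with fixed random seeds.

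Shares of cells have exact binomial 95% intervals. UMIs were summed per class and library and scaled to CPM, with exact Poisson intervals for levels and exact conditional binomial intervals for ratios. Classes with at least 100 cells in every library were compared, which were 5: tumour-, T, NK and B cell-like cells and monocyte- or macrophage-like cells. Log2 ratios used a pseudocount of 10 CPM. For 23 gene lists, members with at least 10 CPM in the mean of the 4 libraries were measured, and the median log2 ratio was placed among 10000 random lists of the same size drawn in 20 bins of expression. A member or gene was called higher or lower at 1.5-fold, which is a rule of size and not a test. For the cell cycle, cells were thinned to 1500 UMIs (tumour-like) or 800 UMIs (other classes), shallower cells were left out, and cells with at least 3 UMIs of the G2/M list were counted. The profile of free RNA came from barcodes with 10 to 100 UMIs. With 1 library per group no test of a treatment was run, and no p-value was made from cells.

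The comparisons were each treated group against control and the combination against each single agent. Named genes are, for each treated group against control, the 6 highest and 6 lowest log2 ratios in tumour- and T cell-like cells, and for YKL-5-124 and the combination the 3 highest and 3 lowest in the other classes. They needed at least 50 CPM in either library and 50 UMIs in both together. Mitochondrial, ribosomal protein and Y-linked genes, Xist, antigen receptor and haemoglobin genes and markers of other classes were left out. Up to 4 members with the largest ratios were named per list described, and Cdk7, Pdcd1, Cd274, Cxcl9, Cxcl10, Ifng, Gzmb, Mki67 and Top2a wherever measured. Cxcl9 was below the CPM minimum in the classes compared. Some genes of this rule are left out of the text for length, and some are not reported here. The granule genes Elane, Mpo, Prtn3 and Ctsg as a set, the Gzmc-high sub-cluster, Foxp3, the cell counts of Retnla and Arg1, S100a8 and S100a9 in free RNA and the 8 tumour genes shared by the treated libraries were picked out after their values were seen. Cell filters, marker and gene lists, comparisons, the naming rule and all alternatives but those listed below as added were chosen before the data were examined.

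The ratio and list steps were tested on simulated Poisson counts drawn from the real means and library sizes of YKL-5-124 against control. These counts had no spread between cells, which is also what the intervals assume. The coverage found is thus set by the model and does not extend to genes whose UMIs lie in few cells. In tumour-like cells, with 8939 genes, the intervals held the true ratio of 95.4% of unchanged genes, and 7.46%, 85.1% and 100% of genes changed 1.5-, 2- and 4-fold passed the size rule. In T cell-like cells, with 6817 genes, these values were 95.8%, 26.9%, 80.6% and 100%. Of unchanged lists, 5% and 4.5% lay outside the middle 95% of random lists, and 100% of lists raised 1.5-fold lay above it in both classes.

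The alternatives tried were a minimum of 1000 UMIs, a high minimum set from the 99th percentile of the largest barcodes (5728, 4756, 4474 and 4704 UMIs in control, anti-PD-1, YKL-5-124 and the combination), mitochondrial limits of 5% and 20%, doublets kept, Leiden resolutions of 0.5 and 2, and other denominators of shares. For ratios they were median-of-ratios scaling, free RNA subtracted, cells weighted equally, cells thinned, a pseudocount of 1 CPM, CPM minimums of 50 and none, and other UMI minimums for the cell cycle. Added after seeing the data were the settings without single clusters or sub-clusters, with 1 cluster only, without granule-gene cells, with at least 10 cycle UMIs in tumour-like cells, and with cells outside the neutrophil-like and the monocyte- or macrophage-like classes as denominator. Their effect is given in the closing section. Antigen receptor sequences and other experiments of the study were not analysed here.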

Results

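Single-cell RNA sequencing was done on mouse lungs carrying small cell lung cancer (SCLC), after tumour cells had been injected orthotopically into the lung. The control group received vehicle and isotype IgG. The other groups received anti-PD-1 antibody (200 µg per mouse), which blocks an inhibitory receptor of T cells, YKL-5-124 (10 mg/kg), an inhibitor of the kinase CDK7, or both, called the combination here. Each group has 1 library, so no value below has a replicate error, and differences between libraries could not be set against differences between animals. The libraries held 22384282 unique molecular identifiers (UMIs) in control, 17329001 with anti-PD-1, 22357198 with YKL-5-124 and 22950622 in the combination. The filters kept 3384, 2676, 4014 and 3911 cells in the same order, 13985 in total, with median depths of 1913, 1921.5, 1970 and 2193 UMIs per cell. Cells fell into 33 clusters, of which all but 2 took the name of a cell class from fixed marker genes. These classes are written as "T cell-like" and so on, since no protein or lineage was measured, and the other 153 cells stayed unnamed. Parentheses after a share, a level or a ratio hold its 95% interval, which covers counting error only, and those after the median of a gene list hold the range from resampling its members. Gene levels are given as CPM, UMI counts scaled to the total of a class in a library, and a gene counts as higher or lower when its smoothed ratio reaches 1.5-fold.

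**Figure D1:**
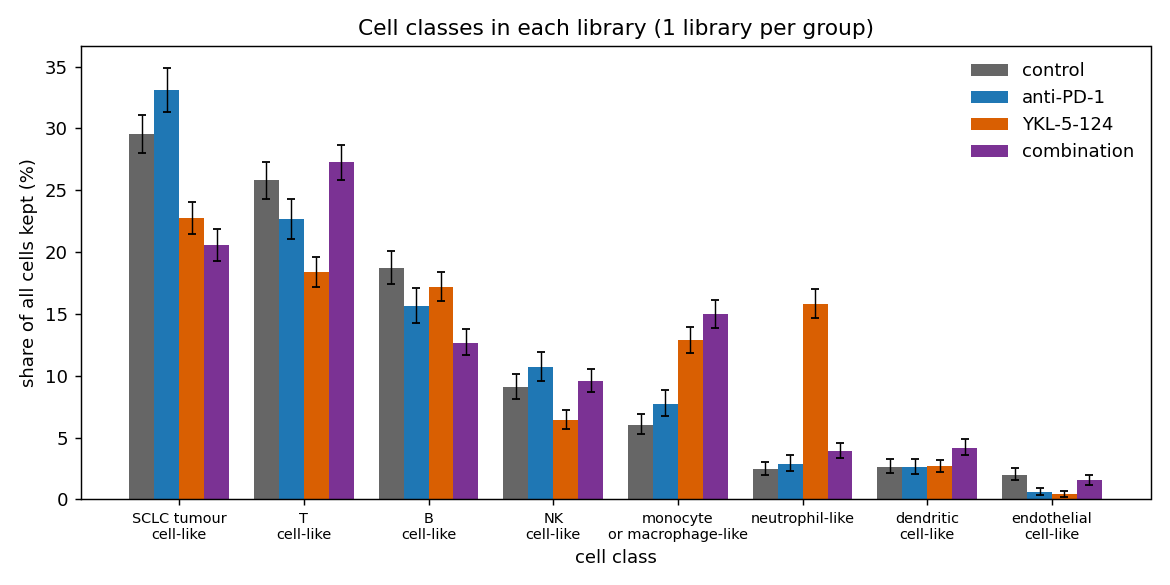
Bars give the share of all cells kept (%) that each of 8 cell classes took in each library, with exact binomial 95% intervals, 1 library per group. Neutrophil-like cells made up 15.8% of the YKL-5-124 library and at most 3.91% of the others, and tumour-like cells took 22.7% of it and 20.6% of the combination, against 29.5% in control. All shares of a library add up to 100%, so a larger class lowers the others.

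The comparison of YKL-5-124 with control asks what inhibition of CDK7 alone does to tumour and immune cells. In the YKL-5-124 library the neutrophil-like and the monocyte- or macrophage-like classes were larger, and the tumour, T and NK classes took smaller shares of all cells. Neutrophil-like cells, the short-lived granulocytes of the first immune response, made up 15.8% of cells (14.7 to 16.99) against 2.42% (1.93 to 2.999) in control, a 6.53-fold share (5.18 to 8.32). Monocyte- or macrophage-like cells made up 12.9% (11.8 to 13.9) against 6.03% (5.25 to 6.88), a 2.13-fold share (1.81 to 2.52). SCLC tumour cell-like cells, which carry the neuroendocrine genes of this cancer, made up 22.7% (21.4 to 24.0) against 29.5% (28.0 to 31.1), a ratio of 0.770 (0.703 to 0.843). T cell-like cells made up 18.4% (17.2 to 19.6) against 25.8% (24.3 to 27.3), a ratio of 0.712 (0.644 to 0.786). Among cells outside the 2 myeloid classes, the neutrophil-like and the monocyte- or macrophage-like, these ratios were 0.988 (0.902 to 1.08) for tumour-like, 0.914 (0.827 to 1.01) for T cell-like and 0.9099 (0.768 to 1.08) for NK cell-like cells. Under a high minimum of 5728 UMIs in control and 4474 with YKL-5-124, which left 662 and 985 cells, the T cell-like ratio was 1.46 and the monocyte- or macrophage-like ratio 7.31, while the neutrophil-like ratio of 32.9 and the NK cell-like ratio of 8.07 each rest on 1 cell of control.

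The neutrophil-like cells lay in 2 clusters. Cluster 8 held 380 cells of the YKL-5-124 library and 82 of control. Cluster 13, rich in the granule genes Camp, Ngp and Ltf of immature neutrophils, held 255 cells of the YKL-5-124 library, 13 of the combination, 1 of anti-PD-1 and 0 of 3384 in control, which allows a share of up to 0.109%. A cluster that comes almost whole from 1 library may stand for that library and not for a cell type. Neutrophil-like cells had median depths of 1555 UMIs against 940.5 in control, and with a minimum of 1000 UMIs per cell their ratio was 13.6. Counted from 100 UMIs up, barcodes rich in S100a8 and S100a9 were 4.17-fold as many per cell kept (3.48 to 5.04). NK cell-like cells were at 6.45% (5.71 to 7.26) against 9.10% (8.15 to 10.1). Endothelial cell-like cells, the lining of vessels, numbered 16 against 67, a ratio of 0.201 (0.109 to 0.351), beside 2 against 13 smooth muscle cell- or pericyte-like and 7 against 11 fibroblast-like cells, and antibody-secreting plasma cell-like cells 17 against 36, a ratio of 0.398 (0.210 to 0.727).

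T cell-like cells of the YKL-5-124 library carried more RNA of proliferation genes. The G2/M phase list, genes of mitosis, had a median log2 ratio of 1.11 (0.84 to 1.33), with 38 of 44 measured members at least 1.5-fold higher and 0 lower. Mki67, the nuclear proliferation marker, was at 122 CPM against 22.4, a ratio of 5.45 (3.95 to 7.66). Birc5, a component of the chromosomal passenger complex, had a ratio of 5.20 (4.04 to 6.77), Top2a, the topoisomerase that untangles replicated DNA, 4.08 (3.33 to 5.04), and Ccnb2, a mitotic cyclin, 3.95 (2.99 to 5.30). The G1/S and S phase list had a median of 0.68 (0.51 to 0.87), with 21 of 34 members higher. In it, Rrm2, a subunit of ribonucleotide reductase, was at 169 CPM against 37.3, and Mcm5, part of the replicative helicase, at 87.8 against 27.9. The replication-linked histone genes Hist1h1b and Hist1h2ap were 7.32-fold (5.37 to 10.2) and 6.20-fold (4.08 to 9.79) higher. Of T cell-like cells thinned to 800 UMIs, 23.4% (20.3 to 26.6) held at least 3 UMIs of the G2/M list in the YKL-5-124 library and 15.96% (13.6 to 18.6) in control. At least 5 UMIs were held by 9.27% (7.25 to 11.6) and 2.70% (1.72 to 4.02), and without thinning 63.1% and 60.5% held at least 3. In B cell-like cells thinned alike, which had median depths of 1452 and 1509 UMIs against 1999 and 1968 in T cell-like cells, 11.6% and 11.7% held at least 3 and 1.47% and 0.489% at least 5. The cluster of T cell-like cells richest in G2/M list UMIs, cluster 21, held 33 cells against 3. Without it the median of the G2/M list was 0.23 and the log2 ratio of Hist1h2ap -0.20. Among sub-clusters of T cell-like cells, a regulatory T cell-like one had Mki67 among its 10 leading genes and held 39 cells against 6. Another, with Rrm2 and Birc5 among its leading genes, took no subset name and held 28 against 7. How the cycle RNA divides between regulatory and other T cell-like cells was not measured.

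Genes of cytotoxic T cells were lower in the same library. The list of cytotoxic effector genes had a median log2 ratio of -0.43 (-0.81 to -0.30), with 8 of 20 members lower and 0 higher. The chemokine Ccl3 was at 6.09 CPM against 130, a ratio of 0.0469 (0.0239 to 0.0834), and its relative Ccl4 had a ratio of 0.186 (0.149 to 0.230). Gzma, a serine protease of cytotoxic granules, was at 343 CPM against 1282, and Gzmb, which triggers apoptosis in target cells, at 230.0 against 424. A sub-cluster of 25 T cell-like cells with high Gzmc, of which 14 came from control and 2 from YKL-5-124, carried much of this. Without it the median was -0.15, Gzmb was no longer lower in the YKL-5-124 library, with a log2 ratio of 0.24, and Gzmc was higher, with 1.00. The sub-cluster was picked by its Gzmc, and Ccl3, Ccl4 and Gzma are also among its leading genes. An upward move of these ratios without it thus follows from the choice and is not a separate result.

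The naive and memory T cell genes had a median log2 ratio of -0.29 (-0.39 to -0.16), with 0 of 14 members past 1.5-fold. Its members with the lowest ratios were S1pr1, the receptor for exit from lymph nodes, at 0.692, and Lef1, a transcription factor of naive T cells, at 0.701. The checkpoint and exhaustion genes went both ways, with a median of 0.09 (-0.39 to 0.30). Lag3, an inhibitory receptor, was at 53.3 CPM against 111, but without the Gzmc-high sub-cluster its log2 ratio was 0.23, while the inhibitory receptor Ctla4 was 1.97-fold (1.65 to 2.36) and the co-stimulatory receptor Tnfrsf4 1.87-fold (1.59 to 2.20) higher. Both Ctla4 and Tnfrsf4 are also markers of regulatory T cells. Regulatory T cell-like cells were 7.19% of T cell-like cells (5.43 to 9.30) against 1.604% (0.879 to 2.68). Foxp3, their lineage factor, was found in 3.39% of T cell-like cells against 2.06%, and after thinning in 1.11% (0.479 to 2.17) against 0.939% (0.406 to 1.84), a difference not detectable at this depth. In B cell-like cells, Foxp3 was found in 1 of 691 with YKL-5-124 and in 0 of 633 in control, an upper limit of 0.581%. Glycolysis and hypoxia genes had a median of 0.29 (0.18 to 0.35), led by Pgk1 and Pgam1, each 1.69-fold higher. The chemokine gene Ccl1 was 7.83-fold higher (4.77 to 13.6). Pdcd1, which encodes PD-1, was at 73.1 CPM against 91.5, and Ifng, which encodes interferon gamma, at 26.4 against 29.3.

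Tumour-like cells, which held 8278245 UMIs against 1969395 in T cell-like cells of the YKL-5-124 library, had smaller list shifts. Their G2/M phase list had a median log2 ratio of 0.27 (0.24 to 0.29), above all 10000 random lists of the same size and expression, but 1 of 54 members reached 1.5-fold. Ccnb1, the main mitotic cyclin, was at 184 CPM against 117, a ratio of 1.57 (1.46 to 1.69), and the kinase Plk1 at 102 against 70.3. With cells weighted equally the median was 0.05. Of cells thinned to 1500 UMIs, 91.4% (88.8 to 93.5) held at least 3 UMIs of the G2/M list against 92.9% (90.7 to 94.7) in control. At least 5 were held by 77.8% (74.2 to 81.1) against 80.3% (77.1 to 83.2), and at least 2 by 97.1% against 96.5%. The MHC class I presentation list, which shows peptides to CD8 T cells, had a median of -0.14 (-0.17 to -0.05), and of 21 members H2-Q7 passed 1.5-fold, at 8.46 CPM against 18.1. The interferon-stimulated genes had a median of -0.08 (-0.23 to 0.01), with the GTPase gene Igtp at a ratio of 0.555 (0.441 to 0.693). Neuroendocrine genes stayed near 0, with a median of -0.03 (-0.06 to 0.02). Cdk7 itself was at 19.2 CPM against 14.7.

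Among single genes of tumour-like cells, the lowest in the YKL-5-124 library was Nupr1. Nupr1, a stress-induced chromatin protein, was at 290.2 CPM against 556, a ratio of 0.522 (0.498 to 0.547). Atf3, a transcription factor of the stress response, had a ratio of 0.678 (0.628 to 0.732), and Eif4ebp1, a repressor of translation, 0.645 (0.563 to 0.738). The epithelial genes Sprr1a and Crct1 were at 0.590 and 0.632, and Nov, a matricellular protein, at 0.658. In the unfolded protein response list (median -0.04, -0.14 to 0.02), Trib3, a pseudokinase of the stress response, was at 26.1 CPM against 47.5. The highest genes were Scand1 (1.98, 1.72 to 2.30), Pcsk1n, a secretory granule protein (1.90, 1.78 to 2.04), C1qbp (1.82, 1.67 to 1.98), D030056L22Rik (1.80) and Pgp (1.70). Of these, all but D030056L22Rik were at least 1.5-fold higher in each of the 3 treated libraries. Of 6 measured inflammatory monocyte genes in tumour-like cells, 3 were higher, with S100a8 at 66.3 CPM against 15.4 and S100a9 at 53.9 against 7.64. These are abundant neutrophil transcripts, and their share of the free RNA of the same library was 4.001-fold that of control (3.86 to 4.15).

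Monocyte- or macrophage-like cells carried less MHC class II RNA, the genes that present peptides to CD4 T cells. The list had a median log2 ratio of -0.99 (-1.06 to -0.26), with 7 of 9 members lower. H2-Aa, a class II alpha chain, was at 1884 CPM against 3949, a ratio of 0.477 (0.455 to 0.5005), and Cd74, the invariant chain, at 9723 against 20001. Cluster 6, rich in F13a1, held most cells of the class in the YKL-5-124 library, 300 of 516, whereas cluster 9, rich in Treml4, held the most in control, 82 of 204. In cluster 6 alone the median was -1.46. The granule protease genes Elane and Ctsg, of early neutrophils and their precursors, were at 272 and 170.1 CPM against 1.38 each, and Mpo, the myeloperoxidase, at 209.6 against 0, with an upper limit of 5.09. At least 3 UMIs of Elane, Mpo, Prtn3 and Ctsg were held by 27 of 516 such cells in the YKL-5-124 library and 0 of 204 in control, an upper limit of 1.79%, and by 0 of 691 and 0 of 633 B cell-like cells. The median depths were 4163.5 and 3382 UMIs, and after thinning the count was 5 of 510. Without these cells the log2 ratio of Elane was -0.12. The lowest genes were H2-M2 (0.123), the eosinophil chemokine Ccl24 (0.283) and Hebp1 (0.272), and in cluster 6 alone Hebp1 was higher, with a log2 ratio of 1.05.

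In NK cell-like cells the G2/M phase list had a median log2 ratio of 0.50 (0.27 to 0.96), with 18 of 38 members higher, led by Cdk1, the mitotic kinase, at 54.3 CPM against 7.37. The Mki67 ratio was 2.62 (1.21 to 6.14) and that of Hist1h1b 6.86 (3.07 to 18.1). Cluster 32, the NK cell-like cluster richest in these genes, held 7 cells against 2, and without it the median was -0.15 and the log2 ratio of Mki67 -0.07. Xcl1, a chemokine that attracts dendritic cells, was at 334 CPM against 748, a ratio of 0.446 (0.370 to 0.536), while Gzmb was at 2324 against 2300.0. In B cell-like cells, the phosphatase gene Dusp1 was 2.40-fold (1.90 to 3.06), S100a6 2.39-fold and the RNA-binding protein gene Khdrbs1 2.24-fold higher, and Rgs1 and Rgs2, regulators of G protein signals, were at 0.335 and 0.435. The heat shock gene Hspa1a was at 8.50 CPM against 91.9 in B cell-like cells, at 16.1 against 82.9 in NK cell-like cells and at 28.4 against 84.5 in T cell-like cells.

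The comparison of anti-PD-1 with control asks what the antibody alone does. The shares of tumour-, T and B cell-like and of monocyte- or macrophage-like cells differed from control by more than counting error. The B cell-like ratio was 0.837 (0.738 to 0.949). The NK cell-like ratio was 1.17 (0.996 to 1.38), with an interval that included equal shares. Tumour-like cells made up 33.1% (31.3 to 34.9) against 29.5%, a ratio of 1.12 (1.02 to 1.23), but without the shallowest tumour cluster, whose median depth was 850.5 UMIs, the ratio was 0.926. That cluster held 51.2% of tumour-like cells with anti-PD-1 and 36.5% in control. T cell-like cells had a ratio of 0.878 (0.790 to 0.9748), monocyte- or macrophage-like cells 1.28 (1.05 to 1.56), neutrophil-like cells 1.19 (0.859 to 1.64) and endothelial cell-like cells 0.283 (0.150 to 0.501). The high UMI minimum, 4756 here, left 575 cells with anti-PD-1. Under it the tumour-like ratio was 0.854, the T cell-like ratio 1.43, the B cell-like ratio 1.22 and the monocyte- or macrophage-like ratio 2.23.

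With anti-PD-1, both cell cycle lists of T cell-like cells had medians near 0. The G2/M phase list had a median log2 ratio of -0.02 (-0.13 to 0.04), with 0 of 44 members past 1.5-fold either way, and the G1/S and S phase list 0.03 (-0.13 to 0.15), with 0 of 34. Mki67 was at 33.2 CPM against 22.4, a ratio of 1.49 (0.973 to 2.27). Penk, the gene of the opioid precursor proenkephalin, was 8.22-fold higher (5.70 to 12.2), the chemokine gene Xcl1 2.66-fold (2.32 to 3.05) and Socs1, a brake on cytokine signalling, 3.08-fold (2.06 to 4.69). Penk is a leading gene of a regulatory T cell-like sub-cluster with 13 cells of anti-PD-1 and 8 of control. Regulatory T cell-like cells were 3.63% of T cell-like cells (2.29 to 5.45) against 1.604% (0.879 to 2.68). Prkca, a protein kinase C gene, was 2.43-fold, Ssbp4 2.62-fold and the replication-linked histone gene Hist1h2ap 4.78-fold (3.07 to 7.70) higher, and Serpinb6b, Ramp3 and Lmo4 had ratios of 0.432, 0.451 and 0.485. Ramp3 and Lmo4 are leading genes of a gamma-delta T cell-like sub-cluster, which held 13 of 606 T cell-like cells with anti-PD-1 and 38 of 873 in control. The cytotoxic effector genes had a median of -0.32 (-0.56 to -0.03), with 5 of 20 members lower and 2 higher. In that list Gzmb was at 145 CPM against 424, a ratio of 0.342 (0.293 to 0.397), and Gzmc at 2.66 against 75.6. Without the Gzmc-high sub-cluster, to which anti-PD-1 gave 2 cells, the median was 0.05, and with cells thinned to 1 depth it was 0.09. Checkpoint and exhaustion genes had a median of 0.21 (-0.05 to 0.39), with Tnfrsf4 2.05-fold (1.74 to 2.43) and Cd200 2.30-fold (1.37 to 3.93) higher. Interferon-stimulated genes had a median of -0.14 (-0.24 to -0.09), and Cxcl10, an interferon-induced chemokine, was at 24.6 CPM against 39.8.

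Lists of chaperone genes had negative medians in several classes of the anti-PD-1 library. The heat shock protein list had a median log2 ratio of -0.75 (-0.79 to -0.51) in NK cell-like cells, with 8 of 11 members lower. The medians were -0.54 (-0.71 to -0.44) in B cell-like cells, -0.53 (-0.64 to -0.44) in monocyte- or macrophage-like cells and -0.26 (-0.40 to 0.04) in T cell-like cells. In NK cell-like cells, Hsp90aa1, a core cytosolic chaperone, was at 378 CPM against 659. In tumour-like cells the unfolded protein response list had a median of -0.26 (-0.32 to -0.17), below all random lists, with 0 of 18 members past 1.5-fold. There, Hspa5, the main chaperone of the endoplasmic reticulum, was at 564 CPM against 805, a ratio of 0.700 (0.674 to 0.726), and Pdia6, a disulphide isomerase, had a ratio of 0.748.

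In tumour-like cells of the anti-PD-1 library, the G2/M phase list had a median log2 ratio of 0.15 (0.11 to 0.21) and MHC class I presentation -0.07 (-0.15 to -0.04). The replication-linked histone gene Hist1h2ap was 2.38-fold higher (2.28 to 2.49) and Scand1 2.80-fold (2.43 to 3.22). The chemokine gene Ccl5, abundant in T and NK cells, was 2.26-fold higher (1.94 to 2.64) in tumour-like cells. Eif3f, a translation initiation factor gene, was 1.94-fold higher (1.74 to 2.16). Nupr1 was at 376 CPM against 556, a ratio of 0.677 (0.647 to 0.708), and Atf3, Sprr1a and Crct1 had ratios of 0.671, 0.690 and 0.687. Nupr1, Sprr1a and Crct1 thus had levels below control in tumour-like cells of all 3 treated libraries, which are set against the same control library. With anti-PD-1, none of them reached 1.5-fold. Cd274, the gene of the PD-1 ligand PD-L1, was at 11.5 CPM against 10.3.

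In monocyte- or macrophage-like cells of the anti-PD-1 library the alternative activation and repair genes moved apart, with a median of 0.01 (-0.17 to 0.43), 3 of 16 members higher and 2 lower. Retnla, a secreted protein of alternatively activated macrophages, was at 588 CPM against 13.8, a ratio of 42.6 (22.9 to 89.5), and Arg1, the arginase of the same state, at 324 against 13.8, a ratio of 23.5 (12.5 to 49.6). Retnla UMIs were found in 5 of 207 such cells against 1 of 204, and after thinning in 4 of 201 against 1 of 198. Arg1 UMIs were found in 13 against 3, and after thinning in 10 against 2. In B cell-like cells, the background here, each was found in 1 of 419 with anti-PD-1, and in control Retnla in 0 and Arg1 in 1 of 633. Retnla is also a leading gene of the airway epithelial cell-like cells, of which the anti-PD-1 library held 11 and control 9. Spp1, which encodes osteopontin, was at 29.8 CPM against 157. Cxcl10 was 6.26-fold higher (3.38 to 12.7), at 104 CPM against 16.6. MHC class II presentation had a median log2 ratio of -0.41 (-0.51 to 0.03). In B cell-like cells interferon-stimulated genes had a median of -0.31 (-0.53 to -0.10), with 9 of 35 members lower, among them Isg15, a ubiquitin-like interferon product, at 6.07 CPM against 51.6.

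**Figure D2:**
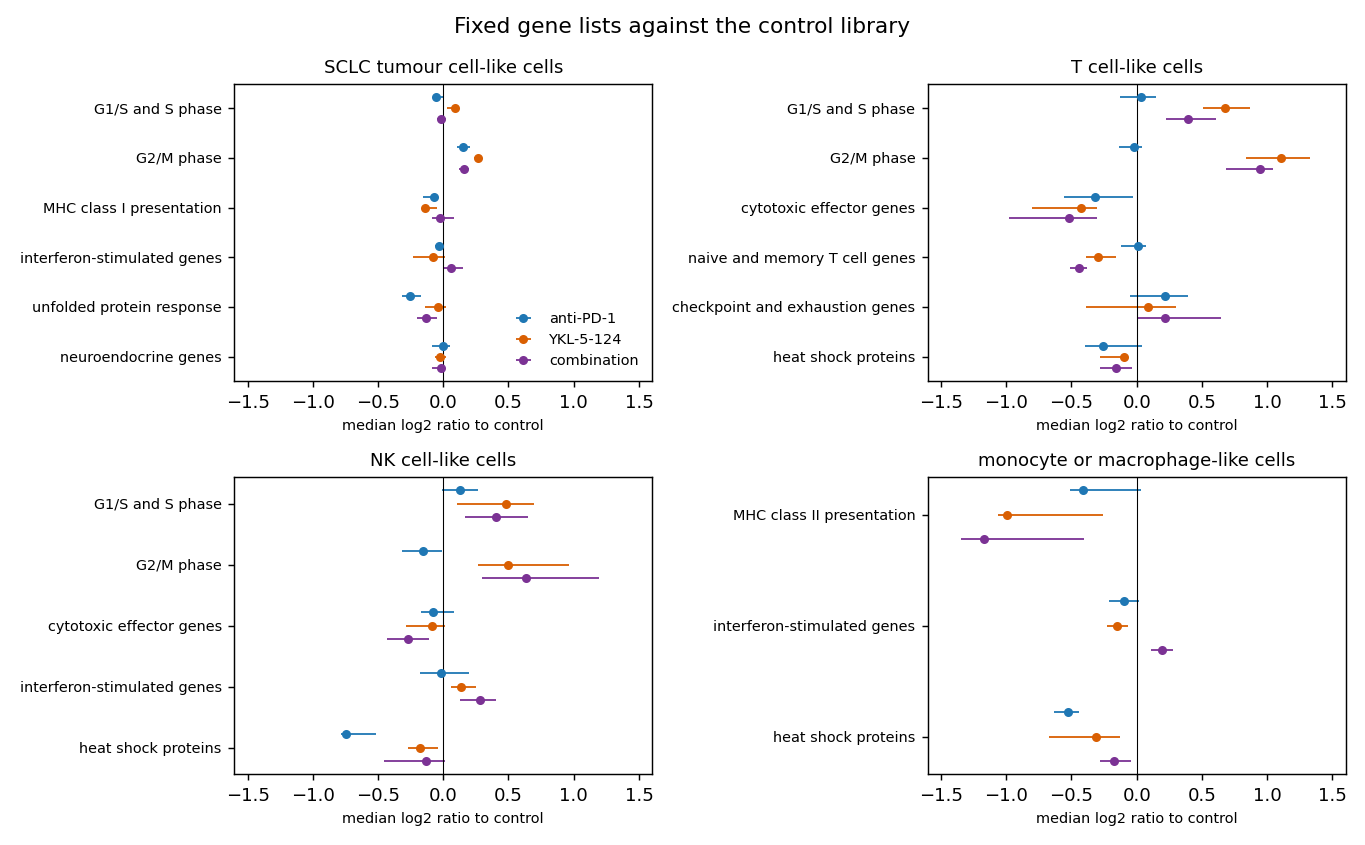
Points give the median log2 ratio to control of fixed gene lists in 4 cell classes for the 3 treated libraries, with bars for the 95% range from resampling the members of a list. In T cell-like cells the G2/M phase medians were 1.11 with YKL-5-124, 0.94 in the combination and -0.02 with anti-PD-1.

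The comparison of the combination with control asks what both agents do together. The combination library had a smaller share of tumour-like cells and a larger one of myeloid cells, and its T cell-like share was close to control. Tumour-like cells made up 20.6% (19.3 to 21.9) against 29.5%, a ratio of 0.696 (0.634 to 0.765), or 0.786 (0.715 to 0.863) among cells outside the 2 myeloid classes. Monocyte- or macrophage-like cells made up 14.96% (13.9 to 16.1), a ratio of 2.48 (2.11 to 2.92), and cluster 6 held the most of them, 285 of 585. Dendritic cell-like cells, the main cells that prime T cells, were at 4.17% (3.56 to 4.84) against 2.63% (2.12 to 3.23), a ratio of 1.58 (1.22 to 2.08). Neutrophil-like cells had a ratio of 1.61 (1.23 to 2.14), or 3.22 with a minimum of 1000 UMIs. T cell-like cells had a ratio of 1.06 (0.965 to 1.16), or 1.19 (1.09 to 1.31) outside the 2 myeloid classes, and B cell-like cells 0.678 (0.602 to 0.764). Under the high UMI minimum, 4704 here, which left 957 cells of the combination, the T cell-like ratio was 3.29, the monocyte- or macrophage-like ratio 4.80 and the neutrophil-like ratio 8.30, the last against 1 cell of control.

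Proliferation genes were higher in T cell-like cells of the combination too. The G2/M phase list had a median log2 ratio of 0.94 (0.69 to 1.04), with 32 of 44 members higher and 0 lower, and the G1/S and S phase list 0.39 (0.23 to 0.61), with 12 of 34 higher. Mki67 was at 114 CPM against 22.4, a ratio of 5.11 (3.75 to 7.13), and Birc5 had a ratio of 4.48 (3.51 to 5.79). Cluster 21 held 56 T cell-like cells of the combination, and without it the median of the G2/M list was 0.07. The regulatory T cell-like sub-cluster with Mki67 among its leading genes held 79 cells against 6. The unnamed one with Rrm2 and Birc5 held 75 against 7. Regulatory T cell-like cells were 10.51% of T cell-like cells (8.73 to 12.5) against 1.604%. Foxp3 was found in 5.16% of T cell-like cells against 2.06%, and after thinning in 1.16% (0.5999 to 2.01) against 0.939%. In B cell-like cells, with a median depth of 1540.5 UMIs against 2318 in T cell-like cells, it was found in 0 of 496, an upper limit of 0.741%. The regulatory and activation receptors Tnfrsf4 (3.69-fold, 3.22 to 4.25), Nrp1 (3.07-fold, 2.11 to 4.57), Ctla4 (2.44-fold, 2.08 to 2.88) and Tnfrsf18 (1.59-fold, 1.42 to 1.77) were the 4 of 14 checkpoint and exhaustion genes that were higher.

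The naive and memory T cell genes had a median of -0.44 (-0.51 to -0.38) in the combination. Ccr7, the receptor for homing to lymph nodes, was at 512 CPM against 858, a ratio of 0.597 (0.558 to 0.639), and Lef1 had a ratio of 0.591 (0.537 to 0.650). Clusters 4 and 7, with Lef1 and Tcf7 among their leading genes, held 22.9% and 16.98% of T cell-like cells there against 36.1% and 22.2% in control. Cytotoxic effector genes had a median of -0.52 (-0.98 to -0.30), with 9 of 20 members lower, and Gzmb was at 146 CPM against 424. Without the Gzmc-high sub-cluster, to which the combination gave 7 cells, this median was -0.15, and with cells thinned to 1 depth it was 0.000786. Under both settings the log2 ratios of Ccl3 and Ccl4 turned positive, at 0.45 and 0.12 without the sub-cluster and 0.84 and 0.04 after thinning. Only Ccl3 after thinning reached 1.5-fold. The highest single genes were Lgals7, which encodes a galectin (13.2-fold, 6.82 to 29.4), and Ccl1 (12.7-fold, 7.95 to 21.7). Lgals7 is a leading gene of a sub-cluster with Il13 and Il4 that holds 35 cells of the combination and 7 of control, and Ccl1 of a regulatory T cell-like sub-cluster that holds 33 and 8. The lowest were Gzmc (0.161), the heat shock gene Hspa1a (0.224) and the tubulin gene Tubb2a (0.326). Without the Gzmc-high sub-cluster, which was picked by that gene, the log2 ratio of Gzmc was 0.50. Pdcd1 was at 135 CPM against 91.5, a ratio of 1.47 (1.24 to 1.76), and Ifng at 23.2 against 29.3.

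Tumour-like cells of the combination showed small list shifts. Their G2/M phase list had a median log2 ratio of 0.16 (0.12 to 0.20), or 0.07 with cells weighted equally, with 0 of 54 members past 1.5-fold. MHC class I presentation was at -0.02 (-0.08 to 0.08) and interferon-stimulated genes at 0.06 (-0.003166 to 0.15). Cxcl10 was at 24.2 CPM against 13.7, a ratio of 1.77 (1.42 to 2.21), but its smoothed ratio did not reach 1.5-fold. Unfolded protein response genes had a median of -0.13 (-0.20 to -0.04), with Trib3 at 15.9 CPM against 47.5 and the asparagine synthetase gene Asns at 132 against 177. Nupr1 had a ratio of 0.487 (0.463 to 0.512) and Cited1, a transcriptional co-activator, 0.689 (0.657 to 0.723). Eif4ebp1, Crct1, Sprr1a and Nov had ratios of 0.595, 0.627, 0.650 and 0.643, and with cells weighted equally the log2 ratio of Crct1 was 0.01. Scand1 was 4.32-fold (3.80 to 4.93) and Pcsk1n 2.91-fold (2.73 to 3.11) higher. The 8 genes at least 1.5-fold higher in tumour-like cells of all 3 treated libraries had a median log2 ratio of 1.14 there, and 5 of them measured in B cell-like cells had 0.87. Of 6 measured inflammatory monocyte genes 5 were higher in tumour-like cells, among them Il1b, an inflammatory cytokine of myeloid cells, at 25.7 CPM against 5.30. The share of free RNA in tumour-like cells was estimated at up to 3.16% there and 1.54% in control.

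In monocyte- or macrophage-like cells of the combination, MHC class II presentation had a median of -1.17 (-1.35 to -0.40), with 7 of 9 members lower. H2-Ab1, a class II beta chain, was at 2091 CPM against 4990 and H2-DMb2, which helps load peptides, at 12.5 against 64.8. In cluster 6 alone the median was -1.40. Retnla was 19.7-fold (10.6 to 41.3) and the monocyte-attracting chemokine gene Ccl7 7.46-fold higher (4.96 to 11.7), while C1qb, a complement subunit, had a ratio of 0.262 (0.233 to 0.295) and the receptor gene Cd72 0.136. In cluster 6 alone Ccl7 was lower, with a log2 ratio of -1.30, and Cd72 was at 0.01. Retnla UMIs were found in 13 of 585 such cells, or 7 of 573 after thinning, and in 3 of 496 B cell-like cells, and the airway epithelial cell-like cells, which also express it, numbered 40 against 9, a ratio of 3.85 (1.84 to 9.01). Cluster 15, rich in C1q genes, held 9.57% of the class against 23.04% in control. Interferon-stimulated genes had a median of 0.19 (0.11 to 0.28), with the antiviral gene Ifit3 1.94-fold higher (1.22 to 3.25).

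NK cell-like cells of the combination had a G2/M phase median of 0.63 (0.29 to 1.19), with 21 of 38 members higher. Their Mki67 ratio was 4.11 (2.08 to 9.01), and without cluster 32, which held 9 cells of the combination, the median was -0.12 and the log2 ratio of Mki67 -0.44. After thinning, 18.2% (14.4 to 22.5) of them held at least 3 UMIs of the G2/M list against 21.5% in control, and 5.15% (3.13 to 7.92) held at least 5 against 1.65%. Their cytotoxic effector genes had a median of -0.27 (-0.43 to -0.11), with Ccl3 at 259 CPM against 773 and Ifng at 88.6 against 182, a ratio of 0.486 (0.352 to 0.669). Hist1h1b was 7.18-fold (3.31 to 18.5), Ccnb2 4.60-fold (2.17 to 11.2) and Eif3f 3.70-fold (2.67 to 5.23) higher, and the survival gene Bcl2a1b had a ratio of 0.421. Eomes, a transcription factor of NK cells, was 1.72-fold higher (1.24 to 2.42). Among B cell-like cells H2-Ke6 was 6.49-fold (3.70 to 12.2), Scand1 3.99-fold (2.60 to 6.29) and Yipf4 3.37-fold (2.13 to 5.46) higher, while Rgs1 had a ratio of 0.362 and Isg15 0.440. With doublets kept, Rgs1 and Isg15 were no longer lower, with log2 ratios of 0.07 and 0.15.

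Against YKL-5-124 alone, which asks what anti-PD-1 adds, the combination had 1.48-fold the T cell-like share (1.35 to 1.63) and 1.48-fold the NK cell-like share (1.26 to 1.74). Outside the 2 myeloid classes these ratios were 1.31 (1.19 to 1.44) and 1.30 (1.11 to 1.53), and under the high UMI minimum 2.26 (1.76 to 2.93) and 1.46 (0.656 to 3.35), the last from 17 and 12 cells. Its neutrophil-like share was lower, with a ratio of 0.247 (0.206 to 0.295), and endothelial cell-like cells numbered 60 against 16. In T cell-like cells Pdcd1 was 1.84-fold (1.52 to 2.24) and Cxcl10 1.69-fold (1.26 to 2.31) higher. The checkpoint and exhaustion genes had a median log2 ratio of 0.41 (0.14 to 0.56) and the G2/M phase list -0.18 (-0.27 to -0.10). Interferon-stimulated genes had positive medians of 0.15 (0.07 to 0.27) in tumour-like cells, 0.14 (0.03 to 0.17) in T cell-like cells and 0.32 (0.26 to 0.41) in monocyte- or macrophage-like cells. Cxcl10 of tumour-like cells was 2.09-fold higher (1.62 to 2.70), at 24.2 CPM against 11.6.

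Against anti-PD-1 alone, which asks what YKL-5-124 adds, the combination had a tumour-like share with a ratio of 0.621 (0.564 to 0.684) and a monocyte- or macrophage-like share with a ratio of 1.93 (1.65 to 2.28). T cell-like cells had a ratio of 1.20 (1.09 to 1.33), endothelial cell-like cells 2.74 (1.53 to 5.19) and neutrophil-like cells 1.36 (1.03 to 1.81). Outside the 2 myeloid classes the tumour-like ratio was 0.684 (0.621 to 0.753) and the T cell-like ratio 1.33 (1.20 to 1.47). Proliferation genes of T cell-like cells were higher, as they were with YKL-5-124 alone against control. The G2/M phase list had a median log2 ratio of 0.84 (0.72 to 1.11), with 35 of 44 members higher and 0 lower, and Mki67 was at 114 CPM against 33.2, a ratio of 3.44 (2.56 to 4.72). Of thinned T cell-like cells, 22.1% (19.6 to 24.8) held at least 3 UMIs of the G2/M list against 16.4% (13.5 to 19.7), and 9.75% (8.01 to 11.7) held at least 5 against 2.74% (1.57 to 4.41). Of B cell-like cells, at least 3 were held by 12.4% and 8.82% and at least 5 by 1.02% and 1.96%. Naive and memory T cell genes had a median of -0.41 (-0.56 to -0.30), and Cxcl10 of T cell-like cells was 2.13-fold higher (1.49 to 3.13), but no longer higher after thinning, with a log2 ratio of -0.33. MHC class II presentation had a median of -0.66 (-0.85 to -0.39) in monocyte- or macrophage-like cells, and Cxcl10 there was at 31.8 CPM against 104, a ratio of 0.307 (0.219 to 0.430). Heat shock proteins had medians of 0.68 (0.32 to 0.77) in NK cell-like cells and 0.55 (0.41 to 0.67) in B cell-like cells. The G2/M phase list of NK cell-like cells had a median of 0.90 (0.66 to 1.15), and without cluster 32 the log2 ratio of their Mki67 was -0.72.

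The layout of the 4 groups allows each agent to be compared with and without the other in pairs that share no library. Across 6817 genes of T cell-like cells, the log2 ratios of YKL-5-124 against control and of the combination against anti-PD-1 had a Pearson r of 0.48 and a Spearman rho of 0.40. Across 8939 genes of tumour-like cells r was 0.31 and rho 0.24. In the other classes r was lower, at 0.12 in B cell-like, 0.13 in NK cell-like and 0.16 in monocyte- or macrophage-like cells. For anti-PD-1 given alone and added to YKL-5-124, r was 0.14 in T cell-like cells and 0.26 in tumour-like cells. It was 0.08 in B cell-like, 0.05 in NK cell-like and 0.04 in monocyte- or macrophage-like cells. Genes are not independent replicates, so no p-value is attached. In T cell-like cells, cell cycle genes moved the same way in both pairs for YKL-5-124, with G2/M phase medians of 1.11 and 0.84.

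**Figure D3:**
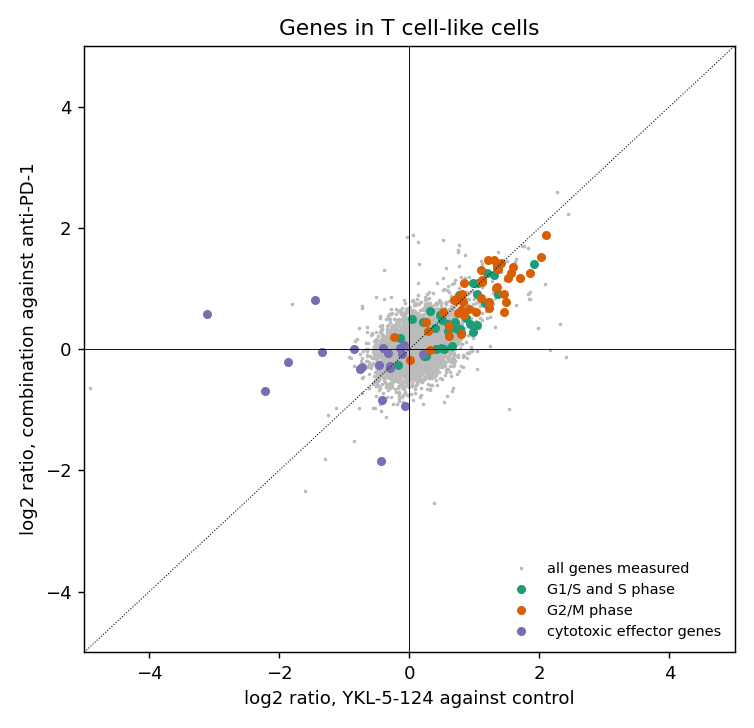
Each point is a gene in T cell-like cells, placed by its log2 ratio for YKL-5-124 against control and for the combination against anti-PD-1, and the dotted line marks equal ratios. Genes of the G1/S and G2/M lists lie to the upper right, with list medians of 0.68 and 1.11 in the first pair and 0.41 and 0.84 in the second.

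In the GRCm38 mouse build, Mki67 (ENSMUSG00000031004) lies on chromosome 7 from 135689784 to 135716361 and Top2a (ENSMUSG00000020914) on chromosome 11 from 98992943 to 99024189. Birc5 (ENSMUSG00000017716) lies on chromosome 11 from 117849251 to 117855743 and Rrm2 (ENSMUSG00000020649) on chromosome 12 from 24708241 to 24714146. The neighbouring genes Ccl3 (ENSMUSG00000000982, 83647844 to 83649355) and Ccl4 (ENSMUSG00000018930, 83662584 to 83664683) lie on chromosome 11, and Gzmc (ENSMUSG00000079186, 56231441 to 56234656) and Gzmb (ENSMUSG00000015437, 56258838 to 56262260) on chromosome 14. Nupr1 (ENSMUSG00000030717) lies on chromosome 7 from 126623249 to 126630861, Scand1 (ENSMUSG00000046229) on chromosome 2 from 156311847 to 156312704 and Pcsk1n (ENSMUSG00000039278) on the X chromosome from 7919822 to 7924410. Cxcl10 (ENSMUSG00000034855) lies on chromosome 5 from 92346638 to 92348889, Pdcd1 (ENSMUSG00000026285) on chromosome 1 from 94038305 to 94052553 and Cdk7 (ENSMUSG00000069089) on chromosome 13 from 100702631 to 100730939. Each is annotated as protein-coding.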

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

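The tests of a library-wide shift, of trends with GC content and length, of fewer tumour cells, of S100a8- and S100a9-rich barcodes, of cells outside the 2 myeloid classes and of thinned T cell-like cells were chosen only after the results they bear on had been seen. With 1 library per group, a difference between animals stays open beside an effect of treatment for every pattern below.

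Some effects of 1 agent went opposite ways with and without the other. For YKL-5-124, the ratio of T cell-like shares was 0.712 when it was given alone and 1.20 when it was added to anti-PD-1, and that of endothelial cell-like shares was 0.201 and 2.74. The heat shock protein list in monocyte- or macrophage-like cells had median log2 ratios of -0.31 and 0.37. For anti-PD-1 given alone and added to YKL-5-124, the ratios were 1.12 and 0.905 for tumour-like shares, 0.878 and 1.48 for T cell-like shares and 0.283 and 3.85 for endothelial cell-like shares. None of these differences was tested, since each ratio rests on 2 libraries. Under the high UMI minimum the T cell-like shares were 1.43, 1.46 and 3.29 of control with anti-PD-1, YKL-5-124 and the combination, and the tumour-like shares 0.854, 0.657 and 0.540, so these contrasts do not hold there. That minimum was highest in control. It left 42, 52, 91 and 200 T cell-like cells in control, anti-PD-1, YKL-5-124 and the combination, so it cannot settle the T cell-like contrasts. Among cells outside the 2 myeloid classes the T cell-like ratios were 0.914 (0.827 to 1.01) and 1.33 (1.20 to 1.47) for YKL-5-124 given alone and added, so the first is no longer clear of 1, and 0.899 (0.809 to 0.998) and 1.31 (1.19 to 1.44) for anti-PD-1. The tumour-like ratio for anti-PD-1 given alone was also 0.926 without the shallow tumour cluster. Among cells outside the 2 myeloid classes, the tumour-like ratios for anti-PD-1 were 1.15 (1.05 to 1.26) given alone and 0.795 (0.723 to 0.876) added to YKL-5-124. The endothelial ratios rest on 67, 15, 16 and 60 cells in control, anti-PD-1, YKL-5-124 and the combination. Other stromal classes had 13, 1, 2 and 9 smooth muscle cell- or pericyte-like and 11, 3, 7 and 20 fibroblast-like cells, so a difference in the yield of stroma stays open. The values for heat shock proteins and for tumour-, T and endothelial cell-like shares come from the same libraries, so they are not independent of 1 unusual library. For T cell-like and for endothelial cell-like shares, the contrasts given for YKL-5-124 and for anti-PD-1 use the same 4 shares. Each is thus 1 contrast seen from 2 sides and not a separate effect of each agent.

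The first pattern is the 8 genes at least 1.5-fold higher in tumour-like cells of all 3 treated libraries, among them Fam174a, Scand1, Pcsk1n, Pi4k2b, Sap30, C1qbp and Pgp. The 3' ends of these genes had a median GC content of 45.3%, inside the 36.1 to 50.2% of random genes matched on expression, and their median transcript length of 2095.5 bases lay inside 1834 to 5005.1, but a median of 8 genes inside such a range excludes nothing. Less the median of the 200 genes nearest in GC content or in length, their median log2 ratio, combination against control, was 1.132 (0.96 to 1.46) or 1.141 (0.99 to 1.49) from 1.135. The trend itself ran only from -0.020 to 0.059 with GC content and from -0.021 to 0.064 with length, too small to be the whole cause. A shift across the whole control library remains, since 5 of the genes could be measured in each other class and had median log2 ratios, combination against control, of 0.87 in B cell-like, 0.92 in NK cell-like, 0.97 in monocyte- or macrophage-like and 1.25 in T cell-like cells, and no test here separates it from an effect of treatment on every class.

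The second pattern is the neutrophil-like share of the YKL-5-124 library. Haemoglobin made up 1.02-fold the share of free RNA found in control (0.973 to 1.07), which argues against more red cell RNA in that library. Haemoglobin traces red cells and not neutrophils, so it cannot tell whether blood-borne neutrophils were left in the perfused lung. The NK cell-like share ratio was 0.709 (8.07 under the high UMI minimum, against 1 cell of control) and the T cell-like ratio 0.712 (1.46), both far from the neutrophil-like 6.53, which argues against a smaller number of tumour cells raising all other classes alike. Neutrophil-like cells were shallower in control, with a median of 940.5 UMIs against 1555, so the UMI minimum removes more of them there, but barcodes with at least 100 UMIs, at least 5 and 3% of them from S100a8 and S100a9, were still 4.17-fold as many per cell kept (3.48 to 5.04), which argues against depth as the whole cause and leaves it open as part. With YKL-5-124 added to anti-PD-1 the neutrophil-like ratio was only 1.36 (1.03 to 1.81), so a rise of this size was seen in 1 library alone. What stays open is an effect of YKL-5-124, blood-borne neutrophils left in the lung, and a difference between animals or in digestion, all untested.

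The third pattern is the higher cycle genes in T cell-like cells of both libraries with YKL-5-124. Tumour marker UMIs in T cell-like cells had ratios of 0.628 (0.493 to 0.796) against control and 0.747 (0.583 to 0.962) against anti-PD-1, so tumour RNA in their droplets was not higher, and cluster 21 held tumour markers at 0.926% of the level in tumour-like cells, which argues against doublets of T and tumour cells. After thinning, the ratios of cells with at least 5 G2/M UMIs were 3.43 and 3.56, with intervals apart in both pairs, which argues against depth as the whole cause. At the 3 UMIs set beforehand the ratios were 1.46 and 1.34, with overlapping intervals in the second pair, and at 5 UMIs B cell-like cells had 1.47% against 0.489% for YKL-5-124 against control. Without cluster 21, which held 33 and 56 cells against 3 in control, the list medians against control were 0.23 and 0.068. A regulatory T cell-like sub-cluster with Mki67 among its leading genes held 6, 9, 39 and 79 cells in control, anti-PD-1, YKL-5-124 and the combination. Its part in the pattern was not measured. An effect of YKL-5-124 and a difference between animals both stay open, untested.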

How the results depend on the processing

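The settings without single clusters or sub-clusters, with cluster 6 only, without granule-gene cells, with at least 10 cycle UMIs and with cells outside the 2 myeloid classes as denominator were chosen only after the results had been seen. No paired analysis was possible because each group has 1 library, and for the same reason leaving out each library in turn was not possible. Of 280 alternative values of the main results, 221 stayed within their counting or member range, 52 moved past it and 7 turned the direction of a value whose own range lay on 1 side of no change. Of 2648 values of other results, 2178 stayed, 439 moved and 31 turned. With free RNA subtracted, at most 20% mitochondrial UMIs or Leiden resolution 2, none of the results recomputed moved past its range. Where no reason is given below, the cause was not tested.

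The high UMI minimum left 662, 575, 985 and 957 cells in control, anti-PD-1, YKL-5-124 and the combination. The ratios of shares to control were then 1.46 (T cell-like), 0.657 (tumour-like), 7.31 (monocyte- or macrophage-like), 32.9 (neutrophil-like) and 8.07 (NK cell-like) for YKL-5-124, the last 2 against 1 cell of control each. For anti-PD-1 they were 1.43 (T cell-like), 0.854 (tumour-like), 2.23 (monocyte- or macrophage-like) and 1.22 (B cell-like), and for the combination 3.29, 0.540, 4.80 and 8.30 in T cell-, tumour-, monocyte- or macrophage- and neutrophil-like cells. With a minimum of 1000 UMIs the tumour-like ratio for anti-PD-1 was 1.02 and the neutrophil-like ratios were 13.6 for YKL-5-124 and 3.22 for the combination. Without the shallow tumour cluster the tumour-like ratios were 0.926 for anti-PD-1 and 0.597 for the combination. Among immune cells the T cell-like ratios were 0.636 for YKL-5-124 and 0.948 for the combination, and among cells other than tumour cells the latter was 0.937, as a smaller tumour share leaves a larger denominator. That share, 1.06 (0.965 to 1.16) of all cells, is counted as moved although it crossed 1. Among cells outside the 2 myeloid classes the tumour-like ratios were 0.988 for YKL-5-124 and 0.786 for the combination, and the T cell-like ratios 0.914 and 1.19. For YKL-5-124 the lower tumour-like share is thus not seen with the myeloid classes set aside, and most of the lower T cell-like share is not.

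List medians in tumour-like cells moved with scaling and depth. For YKL-5-124, the G2/M median was 0.23 with median-of-ratios scaling, 0.050 with cells weighted equally, 0.13 after thinning and 0.29 with a pseudocount of 1, and the MHC class I median was -0.17 with median-of-ratios scaling and -0.20 after thinning. For anti-PD-1, the G2/M median was 0.29 after thinning and the MHC class I median -0.036 with cells weighted equally. For the combination, the G2/M median was 0.068 and the log2 ratio of Crct1 0.0096 with cells weighted equally.

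In T cell-like cells the G2/M median for YKL-5-124 was 0.68 with cells weighted equally, 0.73 after thinning and 1.48 with a pseudocount of 1. Without cluster 21, which was picked as richest in G2/M list UMIs but does not hold all cycling cells, this median was 0.23. For the combination it was 0.68 with equal weights, 1.21 with a pseudocount of 1, 0.068 without cluster 21 and 1.15 without the Gzmc-high sub-cluster. The cytotoxic median for YKL-5-124 was -0.22 with equal weights, -0.22 after thinning and -0.15 without the sub-cluster. For anti-PD-1 it was -0.024, 0.090 and 0.048 under the same settings, and for the combination -0.094, 0.000786 and -0.15. Without the sub-cluster the log2 ratios for YKL-5-124 were 1.00 (Gzmc), 0.23 (Lag3) and 0.24 (Gzmb), that of Ccl3 for anti-PD-1 was 0.91, and those for the combination were 0.50 (Gzmc), 0.45 (Ccl3) and 0.12 (Ccl4). Since the sub-cluster was picked by Gzmc, the move of Gzmc follows from the choice. For the combination, Ccl3 and Ccl4 were at 0.64 and 0.13 with equal weights and at 0.84 and 0.043 after thinning. After thinning, Cxcl10 was at -0.33, combination against anti-PD-1. Without cluster 21, Hist1h2ap was at -0.20 for YKL-5-124 and Gzmb at 0.22 for the combination against YKL-5-124. Ratios of cycling shares were 1.04 for YKL-5-124 against control and 1.05 for the combination against anti-PD-1 without thinning, and 3.43 and 3.56 at 5 or more UMIs.

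In NK cell-like cells without cluster 32, the G2/M medians were -0.15 for YKL-5-124 and -0.12 for the combination. Mki67 was then at -0.074 and -0.44, and at -0.72 for the combination against anti-PD-1, and Top2a at -0.45 for YKL-5-124. Top2a for the combination was at -0.035 after thinning, and with at most 5% mitochondrial UMIs the G2/M median for anti-PD-1 was 0.023. In cluster 6 alone the MHC class II medians were -1.46 for YKL-5-124 and -1.40 for the combination, Hebp1 was at 1.05 for the former, and Ccl7 and Cd72 at -1.30 and 0.010 for the latter. Without granule-gene cells Elane was at -0.12, as those cells were chosen by it. With doublets kept, Rgs1 and Isg15 of B cell-like cells in the combination were at 0.069 and 0.15. Among genes with at least 50 CPM, the correlations of effects with and without the other agent were 0.406 (tumour-like) and 0.622 (T cell-like) for YKL-5-124 and 0.353 and 0.164 for anti-PD-1, over fewer genes.

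Depth limits these results unevenly. The shallowest tumour cluster held 36.5%, 51.2%, 39.0% and 44.7% of tumour-like cells in control, anti-PD-1, YKL-5-124 and the combination. Tumour-like cells had median depths of 5639, 1836, 5284 and 3843 UMIs in control, anti-PD-1, YKL-5-124 and the combination, so thinning to 1500 UMIs left out 320, 405, 332 and 332 cells. At least 10 UMIs of the G2/M list were held by 58.5%, 64.7%, 56.2% and 62.1% of the cells left. NK cell-like cells had the fewest UMIs of the classes compared in every library, 543039, 552958, 497366 and 767207 in the same order.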

Other observations

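No test below was chosen after its result was seen, since none was run here. T cell-like cells of the combination carried more RNA of MHC class II genes, which are abundant in dendritic and B cells, with a median log2 ratio of 0.73 (0.01 to 1.13) and 6 of 10 members at least 1.5-fold higher. The medians were 0.28 (-0.08 to 0.50) with YKL-5-124 and 0.28 (0.13 to 0.39) with anti-PD-1. A sub-cluster of 95 T cell-like cells led by H2-Aa, Cd74 and the B cell genes Cd79a and Igkc, with a median depth of 5322 UMIs, held 20, 16, 28 and 31 cells in control, anti-PD-1, YKL-5-124 and the combination. Doublets of T and B cells in it were not excluded. CD4 T cell-like cells other than regulatory ones were 8.48%, 9.24%, 9.50% and 10.60% of T cell-like cells in the same order. Of them, 7, 3, 5 and 35 cells lay in the sub-cluster led by Il13, Il4, Il1rl1 and Gata3, and 67, 53, 65 and 78 in another. Gamma-delta T cell-like cells, innate-like T cells of the lung, were 5.27%, 2.48%, 5.43% and 3.28%. Clusters covering 66.6%, 65.02%, 61.1% and 56.5% of T cell-like cells took no subset name.

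In tumour-like cells the genes of the CDK-activating and transcription kinases had median log2 ratios of 0.04 (0.01 to 0.12) with YKL-5-124, -0.01 (-0.06 to 0.06) with anti-PD-1 and 0.02 (-0.05 to 0.09) in the combination. The p53 target and DNA damage genes were at 0.05 (-0.02 to 0.11), -0.04 (-0.10 to 0.03) and -0.02 (-0.06 to 0.03), with 0 of 21 members past 1.5-fold in any of the 3. Genes of nucleic acid sensing, such as those upstream of type I interferon, were at 0.05 (-0.06 to 0.16), -0.04 (-0.16 to 0.06) and 0.08, with 0 of 7 members past 1.5-fold in the combination. Group 2 innate lymphoid cell-like cells numbered 31, 23, 37 and 49 in control, anti-PD-1, YKL-5-124 and the combination, fibroblast-like cells 11, 3, 7 and 20, and airway epithelial cell-like cells 9, 11, 16 and 40. In tumour-like cells thinned to 1500 UMIs, 92.9%, 96.5%, 91.4% and 94.3% held at least 3 UMIs of the G2/M list.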
